A study of Mus musculus with 20 samples.

How the data were processed

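Liver RNA of 20 male mice was hybridised to Agilent whole-genome mouse arrays, with 1 dye (Cy3) and 1 array per mouse. The labels place 4 mice in each of 5 inbred strains: C57BL/6 (B6), NZO/HiBomDife (NZO), DBA/2J (DBA), C3HeB/FeJ (C3H) and 129P2/OlaHsd (129Ola). All mice received a high fat diet with 45% fat, and liver was taken at week 6. The labels can be read as week 6 of age or of the diet. The series describes B6 and 129Ola as lean and resistant to diabetes, DBA and C3H as susceptible, and NZO as both obese and susceptible. Mice are named here by strain and the animal number of the labels. The labels give each array an animal number, read here as 1 mouse per array, so p-values measure the spread between mice of these strains, and for the class of susceptible strains the replicate is the strain.

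Per the file headers, the deposited intensity values were made with Agilent Feature Extraction 11.0.1.1 for B6, NZO and DBA and 11.5.1.1 for C3H and 129Ola. Per the submitters' processing notes the version was 9.1, which the headers contradict. Per the file headers, the processed signal used here is a background-subtracted and spatially detrended intensity of each spot, with small values replaced by a surrogate, and with no normalization between arrays. The mean spot intensity and the median local background intensity, deposited in the same files, served as an alternative. Per the file headers, the other columns used hold flags of 0 or 1 for spots well above background, saturated spots and outlier spots. The authors' series value table holds 37892 probes on a linear intensity scale. Its 20 columns hold identical sorted values with a median of 19.9, as quantile normalization gives, and each of the 20 columns correlated best with its own array (lowest rank correlation across probes 0.955). Its background correction and the offset of its scale stay unknown, and its direction is that of the scanner values.

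Each array has 62976 spots, of which 3671 are controls and were left out. Spots with an outlier flag were left out (96 to 186 per array), no spot was saturated, and spots of 1 probe were averaged. Of 55681 non-control probes, 39 had no usable spot on some array and 55642 were kept. The processed signal was taken as log2, and the 75th percentile of each array over all kept probes was subtracted. A probe entered the tests when it was well above background on all 4 arrays of at least 1 strain, which left 28417 probes. Per array, 40.0 to 59.0% of the probes were well above background. On 9 of the 20 arrays (all of C3H and 129Ola and NZO 3) this share was below 50%, so the percentile over the 19935 probes well above background on all 20 arrays was added as an alternative after the data were examined. Array number and signal over background limit the precision of these values.

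Probes were named through their RefSeq accession, which matched the gene table of the GRCm38.p6 assembly for 28011 of 29780 probes that carry one, and otherwise by the name in the files. That table served for names only. Probe coordinates are those of the array files, which use the mouse build mm9. Where a gene had several probes, the probe with the highest mean level over all arrays stood for it. This gave 20609 genes, 15060 of them on 1 probe only and 15193 well above background on all arrays. Probe sequences were not compared with the genomes of the strains, so an allele under a probe can lower its signal in a strain.

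The limma package (3.58.1, R 4.3.3) fitted a mean per strain over all 20 arrays, which share an estimate of the spread (15 residual degrees of freedom, 17.1 with eBayes). All p-values of genes are two-sided, from limma's moderated statistic, and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Log2 differences carry their standard error (SE), with 4 mice per strain. The comparisons were NZO with B6, DBA with B6, C3H with 129Ola, NZO with DBA, and the susceptible with the resistant class. The class difference is the mean of 2 differences, (NZO + DBA)/2 minus B6 and C3H minus 129Ola, each within 1 version of the extraction software, so that an additive effect of the version cancels. A probe not well above background on any array of a group has only a bound there. Its fold is given as "at least N-fold", computed from the mean normalized level of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal well above background and the probe's own signal. For the class, strain means enter this bound with the weights of the class difference. Where only some arrays of a group measured a gene, their number is given.

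The 36 gene lists (pathways, zonation and markers of other liver and blood cells) were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Lists were tested with camera, with the preset correlation of 0.01 between genes, with an estimated correlation, and with fry, and adjusted over the 36 lists of a comparison. Counts "adjusted over the list alone" use the members of a list as the only genes tested. No list was past the threshold with an estimated correlation in any of the 5 comparisons, and the adjusted p under it is given with each list described. The rule named, per comparison, the 8 largest rises and the 8 largest falls past the threshold among genes that carry a gene symbol. These genes had to be well above background on all arrays of the higher group. In the pairs of strains, the groups of mice also had to be free of overlap. For the class, strain means took the place of mice, so mice of the classes can overlap in a named gene. There, the mean of each susceptible strain had to lie on the same side of that of the resistant strain with its software version. For each list described, the rule allowed up to 4 members past the threshold with the largest differences and 1 member that did not pass. Of the members so allowed, those whose call ended without 1 mouse, with scan day as a block or under another background correction were left out of the text after their values were seen. The counts of calls that ended cover them. Some genes that the rule names are not reported here.

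Slides and scan days come from the file headers. B6, NZO and DBA lie on 6 of the 9 slides, 3 of which hold more than 1 strain, and on 3 of the 5 scan days (days 1 to 3). Day 1 holds 2 B6, 3 NZO and 1 DBA, day 2 holds 2 B6, 1 NZO and 1 DBA, and day 3 holds 2 DBA, so values within a day rest on as few as 1 mouse per strain and carry no test. C3H and 129Ola have a scan day and slides of their own, so their difference cannot be told apart from those. Alternatives fixed beforehand were normexp background correction (offset 50), quantile normalization, the array median, the authors' value table, other filters on dim probes, other treatment of several probes per gene, array weights, a 2-fold threshold, the slide as a fixed or random block, the animal number as a block, and leaving out each mouse. Scan day as a block, leaving out slide 3 (NZO 7 and DBA 5, which deviate together from their strains) and leaving out each mouse in the list tests were added after the data were examined. For lists, the scan day block was fitted on the arrays of B6, NZO and DBA alone, so a changed call there reflects fewer arrays as well as the block. Overlaps of comparisons that share B6 were set beside 20 simulations of unchanged groups and beside the 6 splits of the 4 B6 mice.

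The fit was tested on simulated data for NZO against B6, with 200 of 20609 genes changed. Over 20 simulations it recovered on average 33.5% of genes changed 1.5-fold (27 to 41%), 66.6% of those changed 2-fold (58 to 74.5%) and 90.5% of those changed 4-fold (83.5 to 95%), and on average 5%, 4.7% and 4.8% of its calls were false. The simulated noise was independent between genes and arrays and held no effect of slide or scan day. Far more genes were called in the data, so these shares check the fit and do not carry over to the data. The test first asked for over 90% of 4-fold changes in 1 simulation. Single simulations fell on both sides of that mark, so it was replaced, after this was seen, by a mean over 80% in 20 simulations. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Arrays of a strain correlated at 0.972 to 0.993 across probes and no arrays held identical values.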

Results

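The arrays measured liver RNA of 4 mice in each of 5 strains on a high fat diet, B6 and 129Ola as diabetes-resistant strains and NZO, DBA and C3H as susceptible ones. The comparisons ask which liver transcripts differ between each susceptible strain and a resistant strain, between the obese NZO and DBA, and between the classes. C3H and 129Ola differed in 7812 of 20609 genes, 3161 higher in C3H and 4651 lower. NZO and B6 differed in 3768 genes (2002 higher in NZO, 1766 lower) and DBA and B6 in 3166 (1499 higher in DBA, 1667 lower). NZO and DBA differed in 3717 genes, 2011 higher in NZO and 1706 lower. The mice of the compared strains did not overlap for 40.3% of genes in C3H against 129Ola, 22.4% in NZO against B6, 19.7% in DBA against B6 and 20.02% in NZO against DBA, where chance gives 2.86%. A scaling on the probes well above background on all arrays moved the balance of directions to 4529 higher and 2581 lower for C3H against 129Ola. For NZO against B6 it moved to 1557 higher and 2455 lower.

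**Figure D1:**
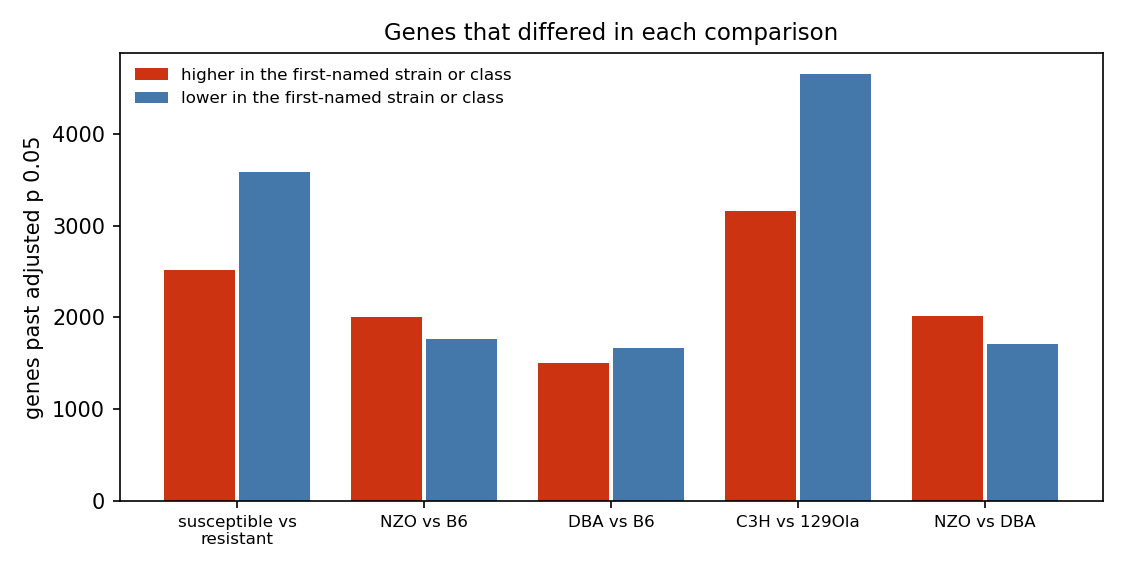
Genes past adjusted p 0.05 (y axis, count of 20609 genes) in each comparison (x axis), higher (red) or lower (blue) in the strain or class named first, with 4 mice per strain. C3H against 129Ola has the tallest bars, 3161 higher and 4651 lower, and with the scaling on probes well above background on all arrays the balance turns to 4529 and 2581 there, to 3217 and 2901 for the class and to 1557 and 2455 for NZO against B6.

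In NZO liver, 12 of 25 measured genes of cholesterol biosynthesis and uptake were higher than in B6, 0 were lower and 13 were not past the threshold, with camera adjusted p = 7.62e-05 and adjusted p = 0.878 with an estimated correlation. Hsd17b7, a reductase of the sterol pathway, was 1.48 ± 0.17 higher on the log2 scale (SE, n = 4 per strain; adjusted p = 5.77e-06). Single genes differed by more. Myom2, a gene of the muscle sarcomere, was 9.16 ± 0.72 higher in NZO (adjusted p = 4.61e-08), with 1 of 4 B6 arrays above background and 4.09 ± 0.35 (SD, n = 4) in NZO. The skeletal muscle markers, which do not include it, were higher in 1 of 14 members, lower in 0 and not past in 13 (1 higher adjusted over the list alone; camera adjusted p = 0.991, and 0.997 with an estimated correlation; median -0.14, mean -0.26, direction up). Their mean was 1.32 in NZO 7 and -2.31 to -1.78 in the other NZO mice. Ifi202b, an interferon-inducible gene known to be silent in B6, was at least 68.8-fold higher in NZO (adjusted p = 2.06e-16), with no B6 array above background. Nuggc, a nuclear GTPase of germinal centre cells, was at least 124-fold higher (adjusted p = 3.1e-14).

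Among the other large rises in NZO, Syt10, a synaptotagmin, was 7.26 ± 0.33 higher, with 2 of 4 B6 arrays above background. Cyp2b10, a drug-inducible cytochrome P450, was 6.04 ± 0.65 higher, with 1 of 4. Hao2, a peroxisomal hydroxyacid oxidase, was at least 35.9-fold higher, and Cyp3a44, a cytochrome P450 mostly of female liver, at least 54.5-fold. Cebpe, a transcription factor of granulocytes, was at least 105.5-fold lower in NZO (adjusted p = 1.83e-12). Ifi27l2b was at least 34.2-fold lower, and Adrb3, the adrenergic receptor of adipocytes, at least 46.0-fold. Other probes gave smaller falls, -2.21 for Ifi27l2b (adjusted p = 0.000236) and -2.31 for Adrb3 (adjusted p = 3.71e-06). Mndal, an interferon-inducible neighbour of Ifi202b, was at least 27.7-fold lower, H2-Q1 at least 13.1-fold and Enpp1, a pyrophosphatase linked to insulin signalling, at least 11.9-fold. Another Enpp1 probe changed by 0.38 (adjusted p = 0.444), so that fall rests on 1 probe. Mx2, an antiviral GTPase, fell by 6.02 ± 0.28 with 1 of 4 NZO arrays above background. Cyp39a1, an oxysterol hydroxylase of bile acid synthesis, fell by 5.62 ± 0.35 and was measured on all arrays of both strains. In mm9 the Mndal probe lies at chromosome 1, 175787550 to 175787609, with that of Ifi202b starting at 175892953. The Cebpe probe lies at chromosome 14, 55329200 to 55329259, and that of Nuggc at 66267169 to 66267228.

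Adjusted over the list alone, 16 members of the cholesterol list were higher in NZO and 0 lower. Acat2, a thiolase of the pathway, was 0.79 ± 0.11 higher. The median of the list was 0.37 among the mice of scan day 1 and 0.67 among those of day 2, and with scan day as a block its adjusted p was 0.000304. Of the interferon response list, 15 of 36 members were higher, 1 lower and 20 not past the threshold (16 higher and 2 lower adjusted over the list alone). Camera gave adjusted p = 0.00716, and adjusted p = 0.943 with an estimated correlation. Mx1 was 2.56 ± 0.30 higher, Ifit1 1.98 ± 0.20 and Igtp 1.37 ± 0.26, while Mx2 was the member that fell. The medians of this list within days 1 and 2 were 0.29 and 0.30, and its adjusted p was 0.00677 with the block, while without B6 11 the call was lost (0.053).

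The fibrosis and hepatic stellate cell list fell in NZO, with 5 of 25 members lower, 0 higher and 20 not past (7 lower and 1 higher adjusted over the list alone). The adjusted p was 7.62e-05 by camera and 0.693 with an estimated correlation. Pdgfrb, the growth factor receptor of stellate cells, fell by 0.98 ± 0.10. The collagen Col6a1 fell by 0.86 ± 0.12, Col3a1 by 0.78 ± 0.20, and Lum, a matrix proteoglycan, by 0.69 ± 0.12. Within days 1 and 2 the medians were -0.51 and -0.17, and with the block adjusted p = 0.000558. Kupffer cell and macrophage markers fell too, 11 of 26 lower, 1 higher and 14 not past (12 lower and 1 higher adjusted over the list alone). Their camera adjusted p was 0.00716, and adjusted p = 0.943 with an estimated correlation. Itgax, an integrin of dendritic cells and macrophages, fell by 2.02 ± 0.42 (2 of 4 NZO arrays above background). Marco, a scavenger receptor, fell by 1.81 ± 0.39 and Trem2, a lipid-sensing receptor, by 1.52 ± 0.36. The medians were -0.55 and -0.17 within the days, with adjusted p = 0.00223 with the block.

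Female-biased liver genes were higher in these NZO males, 7 of 16 higher, 2 lower and 7 not past (8 higher and 2 lower adjusted over the list alone). Camera gave adjusted p = 0.00761, and adjusted p = 0.693 with an estimated correlation. Beside Hao2 and Cyp3a44 they include A1bg, at least 3.64-fold higher (adjusted p = 7.76e-09), and Cyp2b9, at least 5.48-fold higher (adjusted p = 6e-07). Within-day medians were 0.82 and 0.85, and adjusted p = 0.0111 with the block. Cholangiocyte markers fell, 5 of 12 lower, 1 higher and 6 not past (7 lower and 1 higher adjusted over the list alone). For them camera gave adjusted p = 0.00761, and adjusted p = 0.693 with an estimated correlation. Sox9, a transcription factor of bile duct cells, fell by 1.45 ± 0.35 and Prom1 by 0.98 ± 0.16. Within-day medians were -0.54 and -0.51, and adjusted p = 0.00861 with the block. Sinusoidal endothelial cell markers were past the threshold with 1 higher, 2 lower and 17 not past of 20 (1 higher and 5 lower adjusted over the list alone). Here camera gave adjusted p = 0.0431, and adjusted p = 0.943 with an estimated correlation, and within-day medians were -0.19 and -0.26 with adjusted p = 0.046 with the block. That call was lost without B6 9, B6 10, B6 11, NZO 9 or NZO 11 (highest adjusted p 0.193). The oxidative phosphorylation list passed on 2 higher members of 50, with 0 lower and 48 not past (2 higher adjusted over the list alone). Its camera adjusted p was 0.00761, adjusted p = 0.943 with an estimated correlation, and under quantile normalization the call was lost at 0.919. Its within-day medians were 0.22 and 0.01, with adjusted p = 0.0334 with the block, and the call was lost without B6 10 or NZO 3 (highest adjusted p 0.184).

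In DBA liver, 11 of 26 Kupffer cell and macrophage markers were lower than in B6, 2 were higher and 13 were not past, with camera adjusted p = 1.6e-05 and adjusted p = 0.738 with an estimated correlation. Folr2, a folate receptor of resident macrophages, fell by 4.93 ± 0.17 (adjusted p = 7.77e-13). Ifi202b was at least 78.1-fold higher in DBA (adjusted p = 1.43e-16). Ctse, the protease cathepsin E, was at least 73.1-fold higher (adjusted p = 8.63e-14) and Nuggc at least 97.9-fold (adjusted p = 6.5e-14). Cebpe was at least 106.5-fold lower (adjusted p = 1.52e-12).

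Obp2a, an odorant-binding lipocalin, was 7.38 ± 0.76 higher in DBA than in B6, with 3 of 4 B6 arrays above background, and Tmc5 5.71 ± 0.46 higher, with 1 of 4. Corin, a protease that activates natriuretic peptide, was at least 23.03-fold higher, and the defensins Defa29 and Defa38 at least 20.7-fold and 21.6-fold. Zfp874a fell by 6.17 ± 0.50, Mndal fell by 5.88 ± 0.41 and Fbxo44 fell by 4.97 ± 0.45, each with 1 of 4 DBA arrays above background (-3.56 on another Fbxo44 probe). Clec2h fell by 4.99 ± 0.65, with 3 of 4. H2-Q1 was at least 13.2-fold lower, Serpina12, the adipokine vaspin, at least 12.98-fold and the olfactory receptor Olfr1033 at least 10.6-fold.

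Adjusted over the list alone, 13 members of the macrophage list were lower in DBA and 2 higher. Cd52 fell by 2.23 ± 0.21 and Trem2 by 2.01 ± 0.36. Within days 1 and 2 the medians were -0.70 and -0.42, and with the scan day block adjusted p = 2.64e-06. Of the MHC class I and II genes, 7 of 22 were lower, 4 higher and 11 not past (11 lower and 4 higher adjusted over the list alone). The adjusted p was 0.0182 by camera and 0.738 with an estimated correlation. H2-Aa, a class II chain, fell by 3.98 ± 0.39 with 3 of 4 DBA arrays above background, while H2-Ea-ps was at least 3.85-fold higher. H2-K1, a class I gene, fell by 1.78 ± 0.09 on its brightest probe and changed by -1.29 on another (adjusted p = 6.5e-08), whereas 1 more probe was 1.21 higher (adjusted p = 0.000411). Within-day medians of the list were -0.91 and -0.08, and adjusted p = 0.0497 with the block. B6 15 stood apart in the mean of this list (3.8, against 3.17 to 3.24 in the other B6 mice) and in H2-Aa, and without B6 15 the call of the list was lost (adjusted p = 0.0997).

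The xenobiotic cytochrome P450 list was higher in DBA, with 8 of 27 members higher, 1 lower and 18 not past (8 higher and 2 lower adjusted over the list alone). Camera gave adjusted p = 0.0182, and adjusted p = 0.738 with an estimated correlation. Cyp3a44 was at least 15.9-fold higher, Cyp1a2, the caffeine-metabolising enzyme, was 2.23 ± 0.12 higher and Cyp3a13 fell by 2.34 ± 0.16. Within-day medians were 0.22 and 0.17, with adjusted p = 0.0497 with the block, and under quantile normalization the call was lost at 0.0569. DBA 15 stood apart in the mean of this list (5.18, against 4.77 to 4.81 in the other DBA mice), and the call held without each mouse in turn (highest adjusted p 0.0206). Transcripts of the erythroid cell markers were higher in 4 of 8 members, 0 lower and 4 not past (4 higher adjusted over the list alone). For these camera gave adjusted p = 0.0482, and adjusted p = 0.738 with an estimated correlation. Hbb-b2, a globin, was 2.05 ± 0.36 higher and Klf1, a transcription factor of red cells, 1.15 ± 0.22. Within-day medians were 0.46 and 0.85, with adjusted p = 0.0129 with the block. Their call was lost without any 1 of 7 mice, B6 10, B6 15, NZO 3, NZO 7, DBA 5, 129Ola 5 and 129Ola 9 (highest adjusted p 0.338). It was also lost without slide 3 (adjusted p = 0.336), under quantile normalization (0.0798) and with the percentile over probes well above background on all arrays (0.052).

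A further 10 lists that passed for DBA against B6 were not past the threshold with scan day as a block, at medians that in 4 of them were larger in size than without it. The blocked list test used the arrays of B6, NZO and DBA alone, so the lost calls cannot be credited to scan day by itself. Proliferation genes were lower in 9 of 21 members, higher in 1 and not past in 11 (10 lower and 1 higher adjusted over the list alone). Their camera adjusted p was 0.0182, adjusted p = 0.738 with an estimated correlation, and 0.0587 with the block, at within-day medians of -0.46 and -0.44. Mcm6, a subunit of the replicative helicase, fell by 1.77 ± 0.30 and Cdc20 by 1.60 ± 0.35. Plk1, a mitotic kinase, fell by 1.69 ± 0.29 with 3 of 4 DBA arrays above background. Fatty acid oxidation and PPARA targets were higher in 5 of 34, lower in 2 and not past in 27 (6 higher and 2 lower adjusted over the list alone). Their camera adjusted p was 0.0182, adjusted p = 0.738 with an estimated correlation, and 0.0764 with the block, at within-day medians of 0.24 and 0.05. Cyp4a10, an omega-hydroxylase, was 1.94 ± 0.45 higher. The median of the proliferation list was -0.64 without the block and -0.48 with it, and that of the fatty acid oxidation list 0.20 and 0.13, the latter call being lost also without DBA 8 (adjusted p = 0.072).

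The interferon response list, higher in NZO, was lower in DBA than in B6, with 4 of 36 members lower, 1 higher and 31 not past (4 lower and 1 higher adjusted over the list alone). Its camera adjusted p was 0.0329, adjusted p = 0.738 with an estimated correlation, and 0.0764 with the block. Its medians were -0.21, and -0.20 with the block, but of opposite sign within days 1 and 2 (-0.43 and 0.10). The call was lost without B6 10, B6 15, DBA 8 or DBA 9 (highest adjusted p 0.286).

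The other 7 lists had camera adjusted p between 0.0182 and 0.0477, and adjusted p = 0.738 with an estimated correlation (0.796 for oxidative phosphorylation). Sinusoidal endothelial cell markers were lower in 5 of 20, higher in 1 and not past in 14 (6 lower and 1 higher adjusted over the list alone), with a median of -0.21, and -0.27 with the block (adjusted p = 0.0587). Cholangiocyte markers were lower in 3 of 12, higher in 1 and not past in 8 (4 lower and 1 higher adjusted over the list alone), with a median of -0.19, and -0.32 with the block (adjusted p = 0.0587). Fibrosis and hepatic stellate cell markers were lower in 11 of 25, higher in 1 and not past in 13 (11 lower and 2 higher adjusted over the list alone), with a median of -0.13, and -0.22 with the block (adjusted p = 0.103). Male-biased liver genes were higher in 4 of 20, lower in 0 and not past in 16 (4 higher adjusted over the list alone), with a median of 0.23, and 0.20 with the block (adjusted p = 0.0764). Pericentral hepatocyte genes were higher in 6 of 19, lower in 1 and not past in 12 (8 higher and 1 lower adjusted over the list alone), with a median of 0.13, and 0.17 with the block (adjusted p = 0.0859). The tricarboxylic acid cycle and amino acid metabolism list was higher in 6 of 36, lower in 0 and not past in 30 (7 higher adjusted over the list alone), with a median of 0.12, and 0.09 with the block (adjusted p = 0.126). Oxidative phosphorylation genes were higher in 3 of 50, lower in 0 and not past in 47 (3 higher adjusted over the list alone), with a median of 0.10, and -0.01 with the block (adjusted p = 0.859, direction up). Without 1 mouse the call was lost for sinusoidal endothelial markers (B6 10 or DBA 15, highest adjusted p 0.0535), male-biased genes (B6 15, 0.0813), the tricarboxylic acid cycle list (B6 11, 0.05) and oxidative phosphorylation (B6 10, DBA 8 or DBA 15, highest 0.202). For fibrosis markers it was lost without any 1 of 8 mice, B6 10, B6 15, NZO 9, DBA 9, DBA 15, 129Ola 4, 129Ola 5 and 129Ola 9 (highest 0.0808).

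With scan day as a block 2628 genes differed between DBA and B6, 2289 of them called in the same direction without it, and 4189 between NZO and B6, 3559 of them so called. Of the genes called without the block, 3159 and 3148 of 3166 had the same direction within days 1 and 2 for DBA, and 3768 and 3753 of 3768 for NZO. These genes were called from the same mice, so this agreement was nearly fixed beforehand and does not test scan day. With the slide as a fixed block the DBA count was 1181, and with array weights 4848.

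In C3H liver, 23 of 25 genes of cholesterol biosynthesis and uptake were higher than in 129Ola, 0 were lower and 2 were not past, with camera adjusted p = 9.76e-20 and adjusted p = 0.278 with an estimated correlation. Sqle, the squalene epoxidase of this pathway, was 4.67 ± 0.35 higher (adjusted p = 1.94e-08). Cyp4a14, a fatty acid hydroxylase induced through PPARA, fell by 7.67 ± 0.78 (adjusted p = 1.03e-06), with 2 of 4 C3H arrays above background. Dct, a melanin synthesis enzyme, was at least 126-fold higher in C3H (adjusted p = 2.98e-15) and Myom2 at least 159-fold lower (adjusted p = 2.64e-08). Each of these strains lies on its own scan day and slides, and with the slide as a random block 2886 genes were called in place of 7812, fewer than the 4194 of NZO against B6 and the 4001 of NZO against DBA under that setting. No slide holds both C3H and 129Ola, so the setting widens the standard errors of this pair, and fewer calls need not mean smaller differences.

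Against 129Ola arrays not well above background, the bounds on other rises in C3H were at least 86.1-fold for Cacng2, 19.7-fold for the kallikrein Klk1b22 and 20.03-fold for Apol10a. They were at least 12.5-fold for Poln, a DNA polymerase (2.58 on the log2 scale on another probe), 11.7-fold for Tmc5 and 8.98-fold for Serpina12. Tff3, a trefoil factor of mucosal surfaces, was 7.26 ± 0.49 higher and was measured on all arrays. H2-Aa was at least 42.3-fold lower in C3H, Ctse 35.8-fold, Olfr1033 11.1-fold and Tmc7 9.55-fold, though another Tmc7 probe changed by 0.74 (adjusted p = 0.248). Glt1d1 fell by 5.66 ± 0.56 and Gsta2, a glutathione transferase, by 5.47 ± 0.33, each with 3 of 4 C3H arrays above background (-2.87 on another Glt1d1 probe). The Dct probe lies at mm9 chromosome 14, 118412029 to 118412088, the Myom2 probe at chromosome 8, 15133322 to 15133381, and the H2-Aa probe at chromosome 17, 34421285 to 34421344.

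Adjusted over the list alone, 24 members of the cholesterol list were higher in C3H and 0 lower, and the median of the list was 1.90. Cyp51, the lanosterol demethylase, was 3.57 ± 0.29 higher (3 of 4 129Ola arrays above background), Mvd 3.50 ± 0.34 and Fdps 3.02 ± 0.28. Over the scalings tried the median of all genes moved by 0.164, and relative to it the list stayed between 1.52 and 1.98 higher. The mean level of the list was 4.70 ± 0.27 (SD, n = 4) in C3H and 2.81 ± 0.24 in 129Ola. It was 3.68 ± 0.20 in B6, 4.23 ± 0.19 in NZO and 3.86 ± 0.25 in DBA. De novo lipogenesis genes were higher in C3H in 17 of 24 members, lower in 1 and not past in 6 (19 higher and 1 lower adjusted over the list alone). The adjusted p was 3.94e-07 by camera and 0.458 with an estimated correlation. Acacb, which makes malonyl-CoA at mitochondria, was 2.98 ± 0.31 higher, Scd1, the stearoyl-CoA desaturase, 2.81 ± 0.53 and Fasn, the fatty acid synthase, 2.20 ± 0.44.

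**Figure D2:**
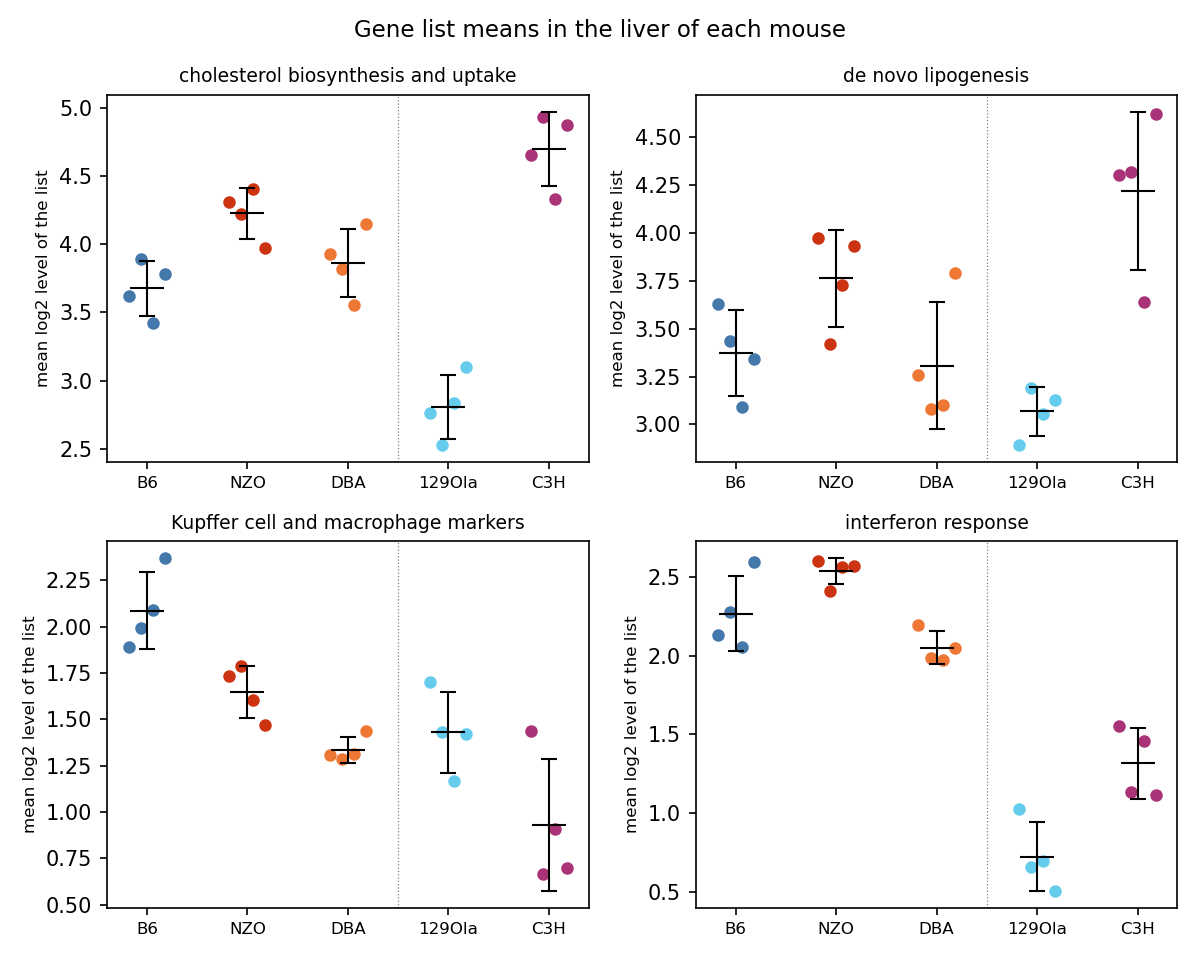
Mean log2 level of 4 gene lists (y axis, log2 signal relative to the 75th percentile of the array) in each mouse (points) of 5 strains (x axis), with mean ± SD bars (n = 4) and a dotted line between the 2 versions of the extraction software. The cholesterol list averaged 4.70 in C3H and 2.81 in 129Ola, and the macrophage list 1.65 in NZO, 1.33 in DBA, 1.43 in 129Ola and 0.93 in C3H.

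Fatty acid oxidation and PPARA targets fell in C3H, with 22 of 34 members lower, 2 higher and 10 not past (24 lower and 2 higher adjusted over the list alone). Camera gave adjusted p = 0.000141, and adjusted p = 0.693 with an estimated correlation. Vnn1, a pantetheinase, fell by 3.07 ± 0.42 and the acyl-CoA thioesterase Acot1 by 2.69 ± 0.40. Xenobiotic P450 genes were lower in 14 of 27 members, higher in 3 and not past in 10 (14 lower and 3 higher adjusted over the list alone), with camera adjusted p = 0.00755 and adjusted p = 0.526 with an estimated correlation. Cyp2c39 fell by 2.98 ± 0.24 and Cyp3a13 by 2.33 ± 0.16. The interferon response list was higher in 18 of 36 members, lower in 0 and not past in 18 (18 higher adjusted over the list alone), with camera adjusted p = 3.94e-07 and adjusted p = 0.526 with an estimated correlation. Oasl1, an antiviral synthetase-like protein, was 2.44 ± 0.17 higher. Interferon-inducible GTPases were higher in 12 of 22 members, lower in 0 and not past in 10 (12 higher adjusted over the list alone), with camera adjusted p = 2.69e-06 and adjusted p = 0.432 with an estimated correlation. Gbp11 was 3.90 ± 0.78 higher and Gbp9 1.46 ± 0.15.

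Markers of other cell types moved in both directions between C3H and 129Ola. Kupffer cell and macrophage markers were lower in 15 of 26 members, higher in 2 and not past in 9 (16 lower and 3 higher adjusted over the list alone), with camera adjusted p = 0.00755 and adjusted p = 0.693 with an estimated correlation. Folr2 fell by 4.30 ± 0.17 and Adgre1, a macrophage surface antigen, by 1.44 ± 0.17, while Marco was 1.35 ± 0.39 higher. Erythroid cell markers were higher in 6 of 8 members, lower in 0 and not past in 2 (6 higher adjusted over the list alone), with camera adjusted p = 0.00871 and adjusted p = 0.458 with an estimated correlation. The globin Hbb-b2 was 1.57 ± 0.36 higher and Hba-a1 1.55 ± 0.35. Adipocyte markers were higher in 4 of 7 members, lower in 1 and not past in 2 (5 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.0168 and adjusted p = 0.296 with an estimated correlation. Without 129Ola 7 the adipocyte call was lost (adjusted p = 0.0605). Adrb3 was 3.58 ± 0.22 higher.

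The glutathione and oxidative stress response list was lower in 12 of 31 members in C3H, higher in 2 and not past in 17 (12 lower and 2 higher adjusted over the list alone), with camera adjusted p = 0.00871 and adjusted p = 0.687 with an estimated correlation. Gstt2 fell by 2.66 ± 0.18. Sinusoidal endothelial cell markers were lower in 11 of 20, higher in 2 and not past in 7 (11 lower and 2 higher adjusted over the list alone), with camera adjusted p = 0.0347 and adjusted p = 0.693 with an estimated correlation. Oxidative phosphorylation genes were lower in 16 of 50, higher in 0 and not past in 34 (16 lower adjusted over the list alone), with camera adjusted p = 0.00948 and adjusted p = 0.693 with an estimated correlation. Under quantile normalization these 3 calls were lost, at 0.0976 for the first and the second and at 0.518 for oxidative phosphorylation, whose direction turned. The endothelial call was lost also without C3H 2, C3H 3, 129Ola 7 or 129Ola 9 (highest adjusted p 0.069), and that of oxidative phosphorylation without 129Ola 7 (0.101). With normexp background correction 4831 genes differed between C3H and 129Ola, and 4133 between NZO and DBA.

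In NZO liver, 19 of 36 interferon response genes were higher than in DBA, 1 was lower and 16 were not past, with camera adjusted p = 1.08e-06 and adjusted p = 0.824 with an estimated correlation. Mx1 was 2.73 ± 0.30 higher (adjusted p = 3.04e-06). Obp2a was at least 325.5-fold lower in NZO (adjusted p = 1.41e-08), its probe at mm9 chromosome 2, 25557738 to 25557797. Myom2 was 8.77 ± 0.72 higher (adjusted p = 7e-08), with 1 of 4 DBA arrays above background. Apol10a was at least 99.6-fold higher (adjusted p = 1.87e-08) and Adrb3 at least 139.8-fold lower (adjusted p = 5.69e-14; -4.73 on the log2 scale on another probe).

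Akr1c18, a progesterone-metabolising reductase, was 6.77 ± 0.40 higher in NZO and Folr2 5.16 ± 0.17, both measured on all arrays. Syt10 was 7.09 ± 0.33 higher (3 of 4 DBA arrays above background), Serpina12 at least 28.5-fold and Tcf24 at least 9.56-fold. Pole4, a subunit of DNA polymerase epsilon, was at least 33.4-fold lower in NZO and Cd207, the langerin of Langerhans cells, at least 25.6-fold. Defa38 was at least 18.6-fold lower, Defa29 17.8-fold and Ifi27l2b 16.8-fold, with -1.28 on another Ifi27l2b probe (adjusted p = 0.0202). Mx2 fell by 6.47 ± 0.28, with 1 of 4 NZO arrays above background.

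Adjusted over the list alone, 22 members of the interferon response list were higher in NZO than in DBA and 1 lower. Ifit1 was 2.17 ± 0.20 higher and Rsad2, which encodes viperin, 1.43 ± 0.23. Within days 1 and 2 the medians were 0.66 and 0.27, and with the scan day block adjusted p = 5.06e-06. MHC genes were higher in 8 of 22 members, lower in 1 and not past in 13 (8 higher and 1 lower adjusted over the list alone). The adjusted p was 0.0122 by camera and 0.859 with an estimated correlation. Within-day medians were 0.47 and 0.16, with adjusted p = 0.0176 with the block.

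Pericentral hepatocyte genes, those of the zone around the central vein, were lower in NZO than in DBA in 8 of 19 members, 0 higher and 11 not past (9 lower and 1 higher adjusted over the list alone). Camera gave adjusted p = 0.000437, and adjusted p = 0.807 with an estimated correlation. Cyp2c37 fell by 3.00 ± 0.22 (-0.87 on another probe, adjusted p = 0.0311) and Cyp1a2 by 2.67 ± 0.12. Slc1a4, an amino acid transporter, fell by 1.71 ± 0.23. Within-day medians were -0.31 and -0.23, with adjusted p = 0.00114 with the block. Xenobiotic P450 genes were lower in 12 of 27, higher in 5 and not past in 10 (13 lower and 6 higher adjusted over the list alone), with camera adjusted p = 0.00278 and adjusted p = 0.807 with an estimated correlation. Cyp2c55 fell by 3.53 ± 0.49 (3 of 4 NZO arrays above background), while Cyp2b9 was at least 4.77-fold higher. Within-day medians were -0.31 and -0.39, with adjusted p = 0.00307 with the block.

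Adipocyte markers were lower in NZO than in DBA on 1 of 7 members, Adrb3, with 0 higher and 6 not past (5 lower adjusted over the list alone). The adjusted p was 0.00769 by camera and 0.207 with an estimated correlation. Their medians within days 1 and 2 were -0.31 and -1.20, and adjusted p = 0.00424 with the block. DBA 5 stood apart in the mean of this list (3.16, against 2.32 to 2.37 in the other DBA mice), and the day 2 median rests on NZO 7 and DBA 5 alone. The call held without DBA 5 (adjusted p = 0.0328). Neutrophil markers were higher in 4 of 10, lower in 1 and not past in 5 (5 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.0342 and adjusted p = 0.859 with an estimated correlation. Camp, the cathelicidin, was 2.29 ± 0.42 higher and Ly6g 1.82 ± 0.16. Cholesterol genes were higher in 4 of 25, lower in 0 and not past in 21 (4 higher adjusted over the list alone), with camera adjusted p = 0.0108 and adjusted p = 0.859 with an estimated correlation. Hsd17b7 was 1.09 ± 0.17 higher, and on other probes 1.01 (adjusted p = 0.000433) and 0.49 (adjusted p = 0.123). Without DBA 8 both calls were lost (0.0784 for neutrophil markers, lost also without NZO 11, and 0.0959 for cholesterol genes). With the block both calls were lost, at 0.11 for neutrophil markers (within-day medians 0.60 and 0.81) and 0.057 for cholesterol genes (0.40 and 0.30). With the block 2732 genes differed between NZO and DBA, 2493 of them called in the same direction without it. Within days 1 and 2, 3717 and 3694 of the 3717 calls had the same direction, which was nearly fixed beforehand, since the calls came from these mice.

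All 25 measured genes of cholesterol biosynthesis and uptake were higher in the susceptible class than in the resistant class (25 higher adjusted over the list alone), with camera adjusted p = 1.83e-20 and adjusted p = 0.247 with an estimated correlation. The mean level of this list was 4.70 in C3H and 2.81 in 129Ola, against 4.23 in NZO, 3.86 in DBA and 3.68 in B6. The class difference includes C3H minus 129Ola, which cannot be told apart from scan day and slide. Sqle was 2.55 ± 0.23 higher (adjusted p = 2.5e-07), Acacb, of fatty acid synthesis, was 1.53 ± 0.21 higher (adjusted p = 2.7e-05), and the macrophage gene Folr2 fell by 3.33 ± 0.11 (adjusted p = 4.74e-13). Sqle and Acacb were not past the threshold in NZO or DBA against B6, and Folr2 was not past it in NZO against B6 (0.23, adjusted p = 0.397). In DBA against B6 this list was not past the threshold, with 2 higher, 2 lower and 21 not past (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0817, and 0.769 with an estimated correlation). In total 6098 genes differed, 2516 higher and 3582 lower in the susceptible class. With strain means as replicates, 3 strains against 2, limma called 0 genes. At an unadjusted p under 0.05 that fit had 713 genes, where 1030.4 would be expected by chance. The 6098 genes thus describe a contrast of these 5 strains and show no effect of the class itself. Of the 10 splits of the 5 strains into 3 and 2, 7 gave as many genes as the real classes, the real split included. So few strains cannot decide whether a class effect exists, and the fit on strain means takes no account of the software version. With the slide as a random block the count was 2997, and with the scaling on probes well above background on all arrays 3217 genes were higher and 2901 lower.

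Dct, Nuggc and Slc26a4, the anion exchanger pendrin, were higher in the susceptible class, each with 4 of 8 resistant arrays above background. The other 4 are all of 129Ola for Dct and Slc26a4 and all of B6 for Nuggc, so the fitted differences (6.14, 4.77 and 3.18 in this order) give no exact size. Cyp3a44 was at least 7.94-fold higher. Adgrv1 was 2.83 ± 0.30 higher, Gbp11 2.78 ± 0.52 and Olfr1466 2.70 ± 0.31 (5 of 8 resistant arrays above background). Tox4 was 3.23 ± 0.14 higher on its brightest probe and changed by -0.32 on another (adjusted p = 0.00178). Olfr1033 was at least 10.8-fold lower in the susceptible class. H2-Aa, Tmc7 and Tmsb15b1 were lower, with 7, 6 and 2 of 12 susceptible arrays above background. No C3H array was above background for them, nor a DBA array for Tmsb15b1, so the fitted -5.02, -3.92 and -4.17 give no exact size. Another Tmc7 probe changed by 0.57 (adjusted p = 0.2), and another Tmsb15b1 probe by -2.72. Gsta2 fell by 4.22 ± 0.22 and Leo1 by 3.25 ± 0.13, each with 11 of 12, and Acot11 by 3.26 ± 0.21 with 10 of 12. Cyp2c23, an arachidonic acid epoxygenase, fell by 3.44 ± 0.12 and was measured on all 20 arrays. In NZO against B6, Gbp11, Olfr1466 and Tmc7 were not past the threshold, nor was Olfr1466 in DBA against B6.

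Of the cholesterol genes, Mvd was 2.14 ± 0.22 higher in the susceptible class, Cyp51 1.97 ± 0.19 (7 of 8 resistant arrays above background) and Fdps 1.87 ± 0.19. In DBA against B6 none of these 3 was past the threshold, nor Cyp51 in NZO against B6. De novo lipogenesis genes were higher in 16 of 24 members, lower in 1 and not past in 7 (18 higher and 1 lower adjusted over the list alone). Camera gave adjusted p = 7.03e-06, and adjusted p = 0.614 with an estimated correlation. Me1, the malic enzyme, was 1.27 ± 0.15 higher and Fasn 1.07 ± 0.29. Pnpla3, a lipid droplet protein, was higher by a fitted 2.35, which is no exact size, with 1 of 8 resistant (none of 129Ola) and 11 of 12 susceptible arrays above background. Neither Me1, Fasn nor Pnpla3 was past the threshold in DBA against B6, nor Fasn in NZO against B6. In the separate comparisons the lipogenesis list was past the threshold in C3H against 129Ola, and in NZO against DBA only with scan day as a block (adjusted p = 0.0271). Without the block it had 5 higher, 1 lower and 18 not past there (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0911, and 0.859 with an estimated correlation). In NZO against B6 it had 5 higher, 2 lower and 17 not past (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.241, and 0.943 with an estimated correlation). In DBA against B6 it had 0 higher, 1 lower and 23 not past (1 lower adjusted over the list alone; 0.699 and 0.915). The interferon response list was higher in 16 of 36, lower in 1 and not past in 19 (18 higher and 1 lower adjusted over the list alone), with camera adjusted p = 4.09e-05 and adjusted p = 0.614 with an estimated correlation. Oasl1 was 1.23 ± 0.11 higher and Igtp 0.96 ± 0.17, while Mx2 fell by 1.29 ± 0.18 (9 of 12 susceptible arrays above background). The fall of Mx2 is that of NZO, since it was not past the threshold in DBA against B6 (0.46) or C3H against 129Ola (0.19), and Oasl1 was not past it in NZO or DBA against B6. In DBA against B6 this list was past the threshold in the opposite direction (camera adjusted p = 0.0329, and 0.738 with an estimated correlation). Interferon-inducible GTPases were higher in 9 of 22, lower in 1 and not past in 12 (9 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.00159 and adjusted p = 0.614 with an estimated correlation. They were not past it in NZO against B6 (0.991, and 0.997 with an estimated correlation) or DBA against B6 (0.118 and 0.738, direction down).

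Markers of several other cell types were lower in the susceptible class. Kupffer cell and macrophage markers fell in 16 of 26 members, with 0 higher and 10 not past (17 lower adjusted over the list alone), with camera adjusted p = 5.35e-06 and adjusted p = 0.614 with an estimated correlation. Cd52 fell by 1.17 ± 0.14, Adgre1 by 1.04 ± 0.11 and C1qb by 0.83 ± 0.13. Sinusoidal endothelial cell markers fell in 10 of 20, with 0 higher and 10 not past (11 lower adjusted over the list alone), with camera adjusted p = 0.00208 and adjusted p = 0.614 with an estimated correlation. Dnase1l3 fell by 1.00 ± 0.10. Cholangiocyte markers fell in 6 of 12, with 0 higher and 6 not past (7 lower adjusted over the list alone), with camera adjusted p = 0.0101 and adjusted p = 0.614 with an estimated correlation. Pkhd1, the fibrocystin gene, fell by 1.46 ± 0.10 (-0.39 on another probe, adjusted p = 0.3) and Spp1 by 1.01 ± 0.11. Pkhd1 was not past the threshold in NZO or DBA against B6, nor C1qb in NZO against B6. In C3H against 129Ola the cholangiocyte list was not past the threshold (0.225, and 0.693 with an estimated correlation). Erythroid cell markers were higher in 7 of 8 members, lower in 0 and not past in 1 (7 higher adjusted over the list alone), with camera adjusted p = 0.000535 and adjusted p = 0.369 with an estimated correlation. Hbb-b2 was 1.51 ± 0.24 higher. In NZO against B6 Hbb-b2 was not past the threshold, nor was the erythroid list (0.057, and 0.878 with an estimated correlation), though the list passed with scan day as a block (adjusted p = 0.0477).

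The glutathione list was lower in the susceptible class in 12 of 31, higher in 2 and not past in 17 (12 lower and 2 higher adjusted over the list alone), with camera adjusted p = 0.0258 and adjusted p = 0.728 with an estimated correlation. Gstt2 fell by 1.09 ± 0.12 and Gstm4 by 0.79 ± 0.08, though another Gstm4 probe changed by 0.17 (adjusted p = 0.169). In DBA against B6, Gstt2 was 1.28 higher (adjusted p = 5.95e-05) and Gstm4 was not past the threshold, nor was Gstt2 in NZO against B6. The glutathione call was lost without 129Ola 7 (adjusted p = 0.067), and the list was not past the threshold in NZO against B6 (0.652, and 0.943 with an estimated correlation) or DBA against B6 (0.29 and 0.796). Genes of bile acid synthesis and transport were lower in 9 of 24, higher in 0 and not past in 15 (9 lower adjusted over the list alone), with camera adjusted p = 0.0474 and adjusted p = 0.614 with an estimated correlation. The sterol transporter genes Abcg5 and Abcg8 fell by 1.32 ± 0.15 and 1.06 ± 0.20, while Abcg8 was not past the threshold in NZO or DBA against B6. This call was lost under quantile normalization (adjusted p = 0.0518) and without slide 3 (adjusted p = 0.0933). It was also lost without any 1 of 9 mice, C3H 1, C3H 5, B6 10, NZO 7, DBA 5, DBA 15, 129Ola 4, 129Ola 5 and 129Ola 7 (highest 0.0829), and the list was past the threshold in none of the 4 comparisons of 2 strains (camera adjusted p 0.121 to 0.669).

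In 366 genes the difference was past the threshold and in the same direction in NZO against B6, DBA against B6 and C3H against 129Ola, 152 higher and 214 lower. Dct was 3.38 higher in NZO, 2.90 in DBA and at least 126-fold in C3H, and Adgrv1 was 2.35, 3.87 and 2.56 higher. Cyp3a44 was at least 54.5-fold, 15.9-fold and 2.14-fold higher, and in C3H its difference was 0.38 on the log2 scale and no longer past with normexp. Cyp2c23 changed by -3.59, -2.79 and -3.69, and Leo1 by -3.02, -2.78 and -3.60 (3 of 4 C3H arrays above background). Olfr1033 was at least 10.5-fold, 10.6-fold and 11.1-fold lower. Independent lists of these sizes would share 22.3 genes higher and 32.2 lower. That mark is too low, since NZO and DBA were both compared with B6 and a gene particular to B6 differs alike in both. Simulated unchanged groups shared 0, but they hold no changed genes and give no mark either. Of the 1284 genes that NZO and DBA shared against B6, 287 went the opposite way in C3H against 129Ola, beside the 366 alike. With the B6 mice split between the NZO and DBA comparisons 239.8 were shared on average, and with the slide as a random block 179 genes were called in place of 366.

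**Figure D3:**
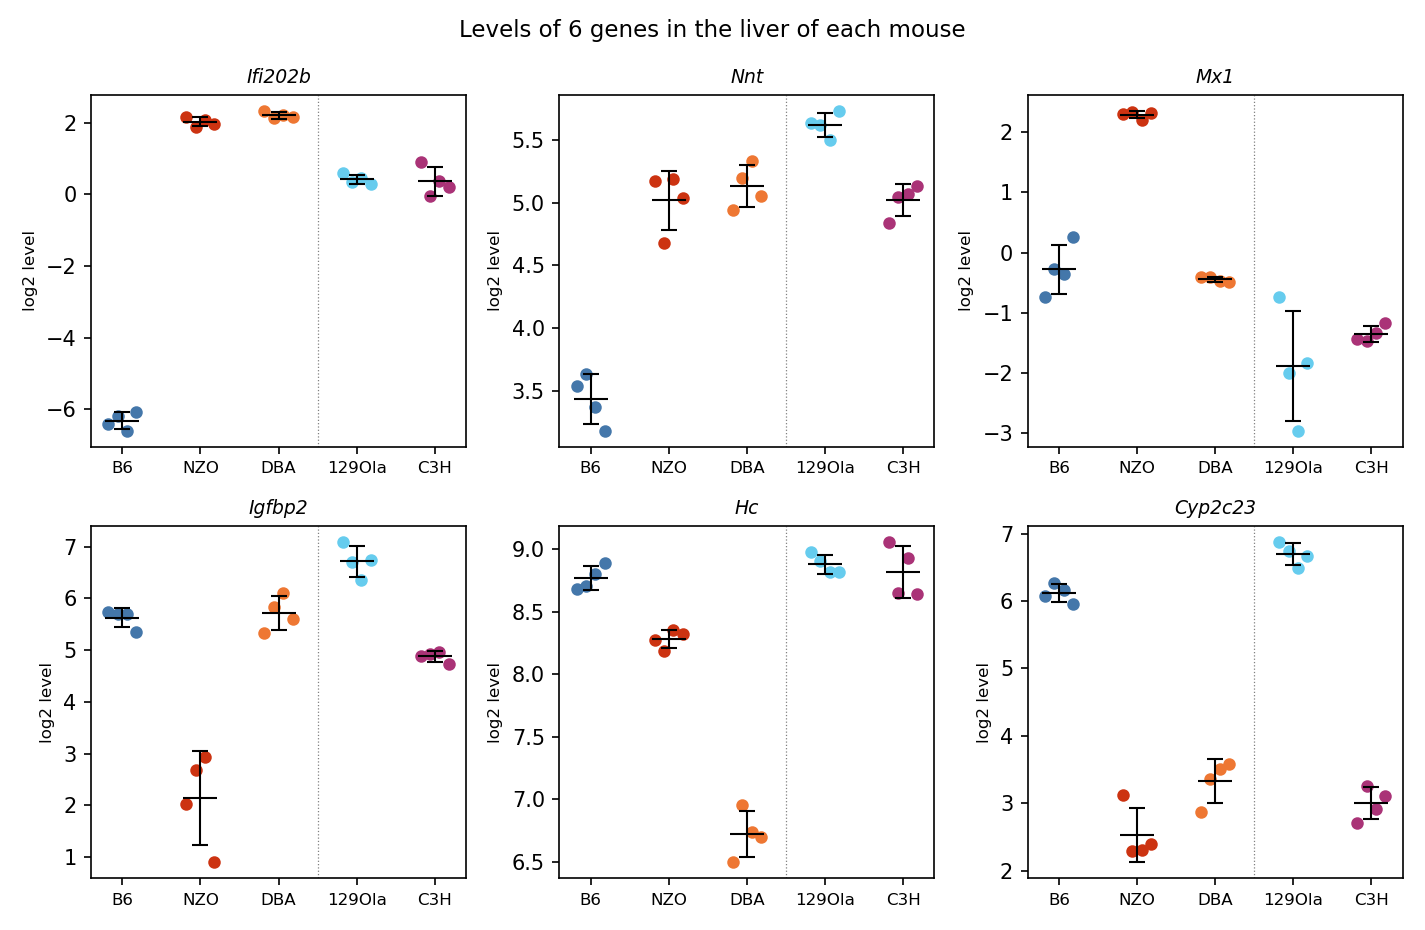
Log2 level of 6 genes (y axis, relative to the 75th percentile of the array) in each mouse (points) of 5 strains (x axis), with mean ± SD bars (n = 4) and a dotted line between the 2 versions of the extraction software. Cyp2c23 averaged 6.12 in B6 and 6.69 in 129Ola against 2.53 in NZO, 3.33 in DBA and 3.00 in C3H, and Ifi202b averaged -6.32 in B6, where no array was above background.

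NZO and DBA shared 1284 genes that differed from B6 in the same direction, 640 higher and 644 lower, against 164 in opposite directions. Independent lists would share 145.6 and 142.8, but a gene particular to B6 differs alike in both comparisons, so that mark is too low. Simulated unchanged groups hold no changed genes, so the 0 they shared was fixed beforehand. Across genes, which are not independent replicates, the log2 differences from B6 correlated at 0.472, where unchanged groups against the same B6 mice gave 0.502. Their covariance was 0.216 against 0.0398 in those simulations. With the B6 mice split between the comparisons 772.7 genes were shared on average and the correlation was 0.366. That split removes the shared mice but not the shared strain, so none of these values tells a trait of NZO and DBA from that of B6. NZO against B6 and C3H against 129Ola, which share no mice, had 863 genes in the same direction and 856 in opposite directions. For DBA against B6 and C3H against 129Ola these were 871 and 817.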

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

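The tests of scan day and slide, of the scaling for the cholesterol genes and of the signal with normexp, and the interval for second probes that resamples genes, were chosen after the results were seen. The requirement of a passing test in the daily rhythm test was also added after its values were seen. The other tests here were planned.

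Among 296 groups of 4 mice, 19 held a mouse far from the other 3, where chance gives about 1 in 20 groups, or 14.8. The ratio of the mouse's gap to the range of its group was 0.885 for C3H 3 in the percentage of probes above background (43.24, against 46.43 to 46.84). For levels of single genes it was 0.835 for Acot11 in C3H 5, 0.846 for Cacng2 in C3H 2, 0.895 for Corin in DBA 5 and 0.873 for Apol10a in DBA 9. It was 0.84 for Serpina12 in DBA 9, 0.869 for Serpina12 in B6 15, 0.853 for Tox4 in B6 15 and 0.876 for Dct in B6 9. In NZO it was 0.888 for Tox4, 0.882 for Cebpe and 0.877 for Obp2a in mouse 9, and 0.884 for Cyp2c23 in mouse 3. B6 15 was apart in H2-Aa (ratio 0.924, level 2.48 against 0.93 to 1.05), in the mean of the MHC list (0.889, 3.8 against 3.17 to 3.24) and in that of the interferon-inducible GTPases (0.88, 2.02 against 1.57 to 1.62). The mean of the adipocyte markers set DBA 5 apart (0.944, 3.16 against 2.32 to 2.37), and that of the xenobiotic P450 genes DBA 15 (0.898).

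For the 16 genes named for the class, the effect in NZO and DBA against B6 was tested against that in C3H against 129Ola. The fitted difference of the effects was past the threshold in 11, including Cyp3a44 and Tmsb15b1, for which it cannot be determined. The difference of the effects (first minus second) was 3.14 ± 0.27 (SE) for Tox4, -3.65 ± 0.63 for Olfr1466 (1 of 4 129Ola arrays above background), 2.501 ± 0.44 for Gsta2 (3 of 4 C3H arrays) and 2.71 ± 0.43 for Acot11 (2 of 4 C3H arrays). In the other 7 genes a whole strain was not above background, so the fitted difference gives no exact size: 6.02 for Nuggc, -5.99 for Dct, -2.27 for Slc26a4, 4.72 for H2-Aa and 2.93 for Tmc7. For Cyp3a44 (fitted 3.16) and Tmsb15b1 (fitted 1.30) this holds for both effects, and their difference is undetermined. The adjusted p of the 11 genes lay between 5.74e-11 and 0.0107 in limma (0.0107 for Cyp3a44 and 0.00831 for Tmsb15b1, which show no difference of known size). In each gene both effects had the same direction, which the rule for naming class genes had required. For Adgrv1, Gbp11, Olfr1033, Cyp2c23 and Leo1 the difference was not past the threshold (adjusted p 0.521, 0.107, 0.134, 0.127 and 0.0527). Over all genes, 6438 differed in this way, and the versions of the extraction software, the scan days and the strains differ together between the 2 effects.

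In each pair of strains, 1 of 35 splits of the 8 mice, the real one, gave as many genes, the smallest share that 35 splits allow. Every other split mixes the strains, so low counts there follow from any difference between the groups of arrays. The splits speak against chance assignment of mice, but cannot tell strain from scan day or slide. NZO against B6 gave 3768 genes (highest other split 106), DBA against B6 3166 (6), C3H against 129Ola 7812 (12) and NZO against DBA 3717 (834). For the class the regroupings of mice do not decide, although 2 of 100 gave as many genes. The real count was 6098, the highest other 6262, from 1 of the 3 regroupings that kept C3H and 129Ola apart, and where these were mixed the highest count was 457. The count thus follows that pair, and the replicate of the class is the strain. For the genes alike in the comparisons with B6 and 129Ola, 1 of 100 regroupings gave as many, with 366 in the real grouping and 0 as the highest other. Regrouping mixes the mice of the strains and leaves few calls to share, so that 0 does not measure the overlap expected of strains that differ. The 10 splits of the 5 strains into 3 and 2 are too few for a share under 0.05, and 7 of them gave as many genes as the real classes (6958, highest other 11622). That highest split sets B6, NZO and DBA against C3H and 129Ola, which is also the split by software version and scan days, and points to a structure of the samples other than the class.

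C3H and 129Ola differed in more genes than the other pairs of strains without a block for the slide, but with the slide as a random block they differed in 2886, against 4194 for NZO and B6 and 4001 for NZO and DBA. Scan day and slide cannot be told apart from the strains here, since each strain has its own. For the same reason the slide block widens the standard errors of this pair, so its lower count need not mean smaller differences. Lower signal of these arrays stays open: over the 15193 genes well above background on all arrays, C3H against 129Ola had 1.97 times the share of calls of the next pair (95% bootstrap interval 1.90 to 2.04; 37.8% against 19.2%), above the bound of 1.5 set beforehand. With normexp background correction, chosen as a check after the first ratio was seen, the ratio was 1.27 (25.1% against 19.8%), below the bound of 1.5. The planned ratio alone would speak against lower signal, but the ratio depends on the background correction, so the question is left open. A difference between these strains stays open and untested.

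A gene that falls against B6 may do so because its probe matches the B6 allele better. For genes with a 2-fold fall in NZO or DBA against B6, a second probe changed the same way in 175 of 307 (57%), and for rises in 166 of 295 (56.3%). A gene that changed in both strains counts in each, which holds for 108 of 494 genes. With genes resampled, the difference was 0.7 percentage points (-8.2 to 9.8, 95% interval). Choosing the brightest probe disfavours mismatched ones, so this cannot decide on mismatch of a single probe. Mismatch under both probes, genes with a single probe and single genes are not covered and stay open. In C3H against 129Ola the shares were 59.2% for falls and 45.5% for rises (two-sided Fisher's exact test, p = 0.00211).

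The cholesterol list was higher in NZO than in B6 and in C3H than in 129Ola. For NZO, the list median was 0.368 within scan day 1 (3 NZO and 2 B6 mice) and 0.67 within day 2 (1 NZO and 2 B6 mice). With scan day as a block the camera adjusted p was 0.000304. These values come from the mice that gave the list call and argue against scan day alone as the cause. A block for the slide was not run in the list tests, so they do not speak on the slide. For C3H, the scaling is argued against, since the list lay at least 1.52 above the median of all genes while the scalings moved that median by 0.164, but scan day and slide cannot be told apart from the strains (list median 1.90). Another state of the daily rhythm stays open: Dbp changed by -2.49 ± 1.23 (adjusted p = 0.118) and Arntl by 1.07 ± 0.65 (adjusted p = 0.204), so the 2-fold opposite changes predicted beforehand were met by the point values, and the requirement that they pass the threshold, which they did not, was added after the values were seen. The circadian clock list, whose passing was the other sign predicted beforehand, was not past the threshold in C3H against 129Ola. A difference in cholesterol synthesis between the strains stays open as a hypothesis, untested.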

How the results depend on the processing

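The scan-day block, the percentile over probes well above background on all arrays, leaving out slide 3, and leaving out each mouse in the list tests were chosen after the data were examined. Counts of genes for the class, the pairs of strains and the genes alike stayed within 1.5 times the reported ones except under these settings. A 2-fold threshold, which is stricter, gave 994 for the class, 1339 for NZO against B6, 1346 for DBA against B6, 2636 for C3H against 129Ola, 1498 for NZO against DBA and 83 alike. With the slide as a random block (correlation 0.379) the counts were 2997 for the class, 2886 for C3H against 129Ola and 179 alike. For DBA against B6 the slide as a fixed block gave 1181 and array weights 4848, and for C3H against 129Ola normexp gave 4831. Strain means as replicates gave 0 class genes in limma (713 at an unadjusted p under 0.05), with fewer replicates. With the animal number as a replicate block the counts were 1442 for the class, 1274, 1333 and 1530 for NZO against B6, DBA against B6 and C3H against 129Ola, and 1333 for NZO against DBA. Since 2 of the 13 pairs of mice with the same number correlated over 0.1, the numbers do not pair the mice, and this loss of calls does not show weaker effects. The cause was not tested for the other counts that moved. Leaving out 1 mouse gave 5176 to 6282 genes for the class, 3043 to 3686 for NZO against B6, 2702 to 3446 for DBA against B6, 6294 to 7438 for C3H against 129Ola, 3003 to 3769 for NZO against DBA and 307 to 388 alike. Of the list tests, 51 passed, against 0 with an estimated correlation, 74 with fry and 44 to 53 without 1 mouse, where 32 of the 51 held without each mouse. Of the 29 of these in comparisons of NZO, DBA and B6, the scan-day block left 8 of 8, 4 of 14 and 5 of 7 for NZO against B6, DBA against B6 and NZO against DBA, 19 in all with lists that newly passed. That blocked list test used the arrays of NZO, DBA and B6 alone. Of 124 named genes 123 to 124 stayed past without 1 mouse, which was nearly fixed beforehand, since they were picked for large differences between these mice. When only probes well above background on all arrays were tested, 19 of the 124 had a value, and all 19 stayed past. Of the 284 pairs of a named gene and a comparison, 8 lost and 4 gained a call without some mouse, and none had a reversed call under the settings followed per gene. These were the background corrections and scalings of the scanner values, the filters on dim probes, scan day, slide 3 and leaving out each mouse. Blocks for slide or animal number, array weights and the authors' value table were not followed per gene. Of 65 pairs with another probe, 2 were past the threshold in the opposite direction there (H2-K1 in DBA against B6, Tox4 for the class). Scan day and the slide as a fixed block could not be estimated for C3H against 129Ola, the class and the genes alike. A fit on the strains compared alone was not run for the class, where it is the same fit. Signal over background limits the dim group of a gene to a bound.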

Other observations

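No test of this part was added after its result was seen, but the genes described here were picked from the lists after their values were seen. Of 23 measured genes with known inherited strain differences, a list fixed before the data were examined, 6 were higher and 5 lower in NZO than in B6, with 12 not past the threshold (6 higher and 7 lower adjusted over the list alone). The list as a set was not past the threshold in this comparison (camera adjusted p = 0.652, and 0.943 with an estimated correlation). Nnt, the mitochondrial transhydrogenase, known to carry a deletion in a B6 substrain, was 1.59 ± 0.12 higher in NZO than in B6 and 1.70 ± 0.12 higher in DBA, and fell by 0.60 ± 0.12 in C3H against 129Ola, each past the threshold. Of the 2 other probes of Nnt, 1 was higher by 2.89 in NZO (adjusted p = 1.31e-07) and by 3.20 in DBA (adjusted p = 3.05e-08). The other was not past the threshold in NZO (0.17, adjusted p = 0.689) or DBA (0.51, adjusted p = 0.198). Igfbp2, which binds insulin-like growth factors, fell by 3.49 ± 0.31 in NZO against B6 (adjusted p = 2.06e-07) and fell by 1.84 ± 0.31 in C3H against 129Ola (adjusted p = 0.000221). In DBA against B6 it changed by 0.09 ± 0.31 (adjusted p = 0.903), and the difference NZO against DBA was -3.58 ± 0.31 (adjusted p = 1.33e-07).

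Hc, complement component C5, with a null allele known in DBA, fell by 2.05 ± 0.11 in DBA against B6 (adjusted p = 1.75e-10). Glo1, the glyoxalase known to be duplicated in DBA, was 1.24 ± 0.09 higher in DBA than in B6 (adjusted p = 8.92e-09). Pctp, a phosphatidylcholine transfer protein, fell by 2.19 ± 0.25 in NZO against B6 (adjusted p = 5.45e-06). Tbc1d1, a gene of glucose uptake, changed by -0.64 ± 0.10 in NZO, -0.79 ± 0.10 in DBA and -0.86 ± 0.10 in C3H, and is among the 366 genes alike. Klrd1, a receptor of natural killer cells, was at least 1.79-fold lower in DBA than in B6 (adjusted p = 4.05e-05). Zfp69, a zinc finger gene, was 1.49 ± 0.47 higher in DBA than in B6 (adjusted p = 0.0368), with 2 of 4 B6 arrays above background.

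Some lists held large changes without passing as a set. In NZO against B6 the glutathione and oxidative stress response list had 5 of 31 members higher, 6 lower and 20 not past (6 higher and 6 lower adjusted over the list alone), with camera adjusted p = 0.652 and 0.943 with an estimated correlation. Gsta2 fell by 4.19 ± 0.33, Gstm6 fell by 3.78 ± 0.15 and Gstm2 fell by 3.05 ± 0.18. Lipid droplet and triglyceride storage genes were higher in 4 of 25, lower in 0 and not past in 21 (4 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.256 and 0.943 with an estimated correlation. Vldlr, a lipoprotein receptor, was 2.96 ± 0.22 higher in NZO than in B6, and in C3H against 129Ola it fell by 4.21 ± 0.22 (3 of 4 C3H arrays above background). Male-biased liver genes had 3 of 20 higher, 3 lower and 14 not past in NZO (5 higher and 3 lower adjusted over the list alone), with camera adjusted p = 0.652 and 0.943 with an estimated correlation. Their median was 0.10 and their mean -0.02, and camera gave the direction up. Susd4 fell by 3.55 ± 0.27 and Mup20 fell by 1.84 ± 0.20 (-0.16 on another probe, adjusted p = 0.527).

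Of the 1284 genes that NZO and DBA shared against B6, 366 were alike in C3H against 129Ola, 287 were past the threshold in the opposite direction and 631 were not past.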
